A study of Homo sapiens with 8 samples.

How the data were processed

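The series measured poly(A) RNA in 8 libraries of human primary pulmonary artery endothelial cells, 4 given DMSO (Control, which the labels also call untreated) and 4 given 1 mM DMOG for 24 h, with stranded TruSeq libraries per the labels' protocols. The labels name no batch, day, donor or pairing, and both groups number their replicates 1 to 4. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie and edgeR without versions, settings or the step each was used for. The genome build and the annotation release are not given in the sources used here, so no coordinates are printed.

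A single table was deposited. Its FPKM values, 1 per gene and library, are fragments per kilobase of transcript scaled to library size, made by the authors, per the file headers, and a gene without signal carries the placeholder 0.0001. The deposited fold change is the ratio of the mean DMOG FPKM to the mean Control FPKM, and the deposited log2 value is the log2 of that ratio, per the file headers and recomputed from the values. The deposited p-value and q-value of each gene come from the authors, per the file headers, and the test behind them is not stated. The table holds no read counts, so depth was only estimated, from the smallest step between FPKM values of genes with long transcripts, taking 1 step as 1 fragment: 46.0 to 51.3% of these values lay within 0.1 step of a whole number of steps, against 20.0% if there were no steps. Counting intervals cannot be given from FPKM, and the precision of each value is its SD over the 4 libraries.

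The 58825 genes of the table took their symbols by Ensembl gene ID, 58472 from a table of current names and 345 from GENCODE 29, and 8 kept the name in the file. The deposited table gives 548 protein-coding genes the name of a clone, so its own names were not used. Of all genes 31148 were at the placeholder in every library. Genes with at least 1 FPKM in at least 4 libraries were tested, which left 11209. The test was limma 3.58.1 (R 4.3.3; linear model, moderated with a trend of the variance on the level) on log2(FPKM + 1) with DMOG minus Control as the contrast and no other term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05, and the 2-fold count also required an absolute log2 fold change of at least 1. Adding 1 FPKM shrinks the log2 fold change of genes with low values, so it understates their ratios. The steps were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

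Before the data were examined, 41 gene lists with 977 symbols (976 matched), a panel of 24 genes, the tests and the alternatives were fixed. A list was tested with at least 3 tested members, which 39 lists had, with the camera test of limma at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Beside it stood camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way. By camera 19 lists passed the threshold, and 6 of them also passed with an estimated correlation: HIF targets, glycolysis, 2-oxoglutarate dioxygenases, angiogenesis, DNA replication and the ATF4 list. Counts of members adjusted over the list alone were the same as those adjusted over all genes for 34 of 40 lists, and the other 6 are given beside their lists. Genes were named by a rule: the 10 largest rises and 10 largest falls among changed genes with a proper symbol, at least 5 FPKM in the higher group and no overlap between groups, the panel genes, and members of each list that show which way it went. The nuclear protein-coding genes with the largest falls were added after the values were seen, since mitochondrial transfer RNAs filled the list of falls.

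Other settings fixed beforehand were pseudocounts of 0.1 and 0.01, no filter on low values and a filter at 5 FPKM, TMM rescaling, quantile normalization, limma without the trend, the replicate number as a block, an adjusted p of 0.01, each library left out in turn, and the other set tests. TMM factors had been planned from edgeR, but without counts they were computed on FPKM with separate code, tested on simulated data. Settings that need counts were not run. Rescaling to the sum of nuclear genes, with mitochondrial genes kept or left out, was added after seeing the data. The fit was tested on data simulated from the levels and spreads of these libraries, with 200 of 11209 genes changed, about as many up as down. It recovered 75.8% of changes of 0.5 on the log2 scale, 88.1% of changes of 1 and 98.5% of changes of 2, with 7 false among 182 calls. In the data 8197 genes changed, 6212 of them lower, so these rates do not describe the real comparison. Neither this simulation nor that of the TMM code held such a surplus of lower genes. To look for duplicate libraries, the 12 pairs within groups were compared on 636 genes with a single transcript and at least 50 estimated fragments, and squared differences were 3.12 to 4.26 times the sampling variance, so no pair was as close as sampling noise alone would make it.

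How the authors' counting used strand is not stated, so reads of genes with an annotated antisense or overlapping gene, such as HIF1A, cannot be told apart from those of that gene. Reads of close copies are uncertain in the same way, which concerns SLC2A3 and SLC2A14, HSPA1A and HSPA1B, ribosomal protein genes with their many pseudogenes, and mitochondrial genes with copies in the nuclear genome. Genes on the Y chromosome, XIST and TSIX were left out of every description. Measures of whole libraries were compared by two-sided exact permutation tests over all splits of the 8 libraries, adjusted over 8 measures.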

Results

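Messenger RNA was sequenced from human primary pulmonary artery endothelial cells, the cells that line the artery between the heart and the lungs, kept in culture. The series held 4 libraries of cells given the solvent DMSO (Control) and 4 of cells given 1 mM dimethyloxalylglycine (DMOG) for 24 h. DMOG is a cell-permeable analogue of 2-oxoglutarate that inhibits dioxygenases which use 2-oxoglutarate and iron. These include the prolyl hydroxylases that mark the alpha subunits of the hypoxia-inducible factors (HIF) for degradation. DMOG is therefore used to mimic low oxygen. The comparison asked which transcripts differed between DMOG-treated and Control cells. The table gave FPKM values for 58825 genes and no read counts. The depth of each library was therefore not stated. From the spacing of the smallest FPKM values the depth was estimated at 15.2 to 19.8 M fragments in the Control libraries and 19.9 to 21.7 M in the DMOG libraries. Nothing in the labels says that the 4 replicates of a group were separate cultures or donors, so every p-value here measures only the spread between these libraries, which can be technical.

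DMOG raised the transcripts of HIF targets, glucose transporters and glycolytic enzymes, many of them more than 10-fold, and lowered genes of DNA replication. Less firmly, it raised genes of mitosis and lowered genes of DNA repair, cholesterol synthesis, the interferon response and most transcripts of the mitochondrial genome. The set tests of these last 5 groups were lost with an estimated correlation between genes (adjusted p from 0.06 to 0.339), and those of HIF targets, glycolysis and DNA replication were kept. Of 11209 genes tested, 8197 changed (limma, adjusted p under 0.05), of which 1985 were higher and 6212 lower in DMOG. A change of at least 2-fold was found in 2113 genes, 412 higher and 1701 lower. The median log2 fold change of all tested genes was -0.33. It was 0.03 after rescaling by trimmed mean of M values (TMM) and -0.03 after quantile normalization. With TMM 4158 genes were higher and 3880 lower, and with quantile normalization 3580 were higher and 4071 lower. Both methods center the fold changes by construction, so their even balance does not show whether the surplus of lower genes was real. After rescaling to the sum of nuclear genes, which does not center them, 1783 were higher and 6518 lower. The medians of gene lists below are given relative to the median of all tested genes. The groups were far apart beside the spread within them. The correlation between libraries was 0.976 to 0.985 within groups and 0.870 to 0.880 between groups. In 68.8% of tested genes the groups did not overlap, against 2.86% by chance. The number of genes with at least 1 FPKM was 11389 ± 65.9 (SD, n = 4) in Control and 9823 ± 47.6 (SD, n = 4) in DMOG. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries can give, with an adjusted p of 0.0327 over 8 such measures. A count above a fixed FPKM depends on the scaling, as the surplus of lower genes does, and is no separate support for it. The sum of all FPKM also differed, 265295 to 270999 in Control and 244434 to 251415 in DMOG.

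On the log2(FPKM + 1) scale, among changed genes with at least 5 FPKM in the higher group, the largest rise was that of SLC2A3, which encodes the glucose transporter GLUT3, from 4.89 ± 0.25 FPKM to 367 ± 10.1 FPKM (SD, n = 4), a 75.0-fold difference. That value is uncertain as far as reads were shared with its close copy SLC2A14. ADM, the gene of the vasodilator peptide adrenomedullin, rose from 10.6 ± 1.32 to 632 ± 293 FPKM. Its 4 DMOG libraries lay between 376 and 914 FPKM. VEGFA, encoding a growth factor for endothelium, rose from 0.90 ± 0.16 to 47.1 ± 2.51 FPKM. The 10 genes with the largest rises also held ANKRD37, the lipoprotein lipase inhibitor ANGPTL4, the transcriptional repressor BHLHE40, NOCT, the glucose transporter SLC2A1, NDRG1 and the receptor inhibitor ERRFI1. Their log2 fold changes ran from 4.54 for ERRFI1 to 5.36 for ANKRD37. Of the 10 genes with the largest falls, 8 were mitochondrial transfer RNA genes. MT-TS2 fell from 98.8 ± 18.0 to 0.27 ± 0.28 FPKM and MT-TY from 1204 ± 58.5 to 33.5 ± 3.61 FPKM. The other two were CCL2, encoding a chemokine for monocytes, which fell from 32.5 ± 2.56 to 0.40 ± 0.12 FPKM, and MIR126, the locus of an endothelial microRNA. MIR126 had 39.3 ± 12.4 FPKM in Control, and in DMOG it was at the placeholder value in 3 libraries and at 0.87 FPKM in the remaining one. These are reads of the locus in poly(A) RNA, and the level of the microRNA itself was not measured. Among nuclear protein-coding genes, chosen after their values were seen, KCTD12 fell from 84.6 ± 1.73 to 5.08 ± 0.20 FPKM. MAT2A, which encodes an enzyme that makes S-adenosylmethionine, fell from 57.9 ± 1.07 to 5.18 ± 2.45 FPKM, and GIMAP7, of a family of immune GTPases, fell from 26.2 ± 2.29 to 0.65 ± 0.36 FPKM.

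**Figure D1:**
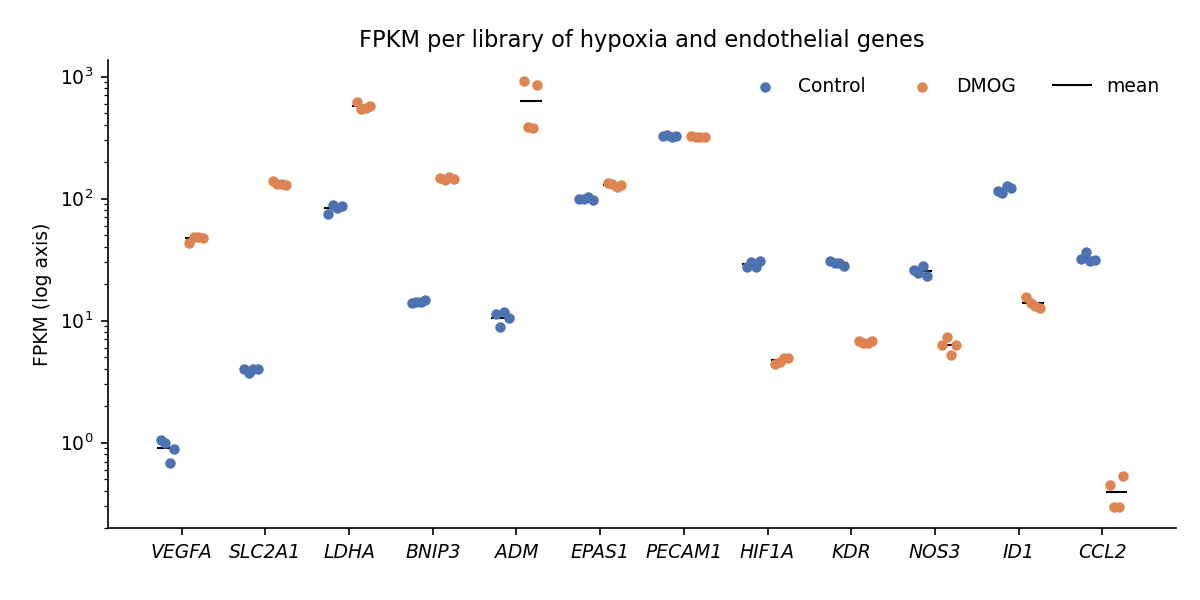
FPKM (log axis) of 12 genes in each of the 4 Control and 4 DMOG libraries, with 1 point per library and a line at the group mean. VEGFA, SLC2A1, LDHA, BNIP3, ADM and EPAS1 rose, HIF1A, KDR, NOS3, ID1 and CCL2 fell, and PECAM1 lay at 326 ± 6.17 FPKM in Control and 320 ± 3.07 FPKM in DMOG (SD, n = 4).

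Known HIF targets rose together. Of 33 tested, 31 rose and 1 fell, WSB1, with a log2 fold change of -0.41 that became 0.02 under TMM. The median log2 fold change lay 2.52 above that of all tested genes (camera adjusted p = 1.44e-24, and 0.000726 as the adjusted p with an estimated correlation). LOX, encoding an enzyme that cross-links collagen, rose from 33.1 ± 1.89 to 624 ± 16.4 FPKM, and BNIP3, a mitophagy receptor, rose from 14.3 ± 0.34 to 146 ± 2.83 FPKM. CA9, a carbonic anhydrase often read as a hypoxia marker, stayed below the expression filter, at 0.02 ± 0.03 FPKM in Control and 0.55 ± 0.21 FPKM in DMOG. Glycolysis genes moved the same way, with 24 of 25 higher. Their median lay 1.71 above that of all genes (adjusted p = 3.41e-20, and adjusted p = 0.00978 with an estimated correlation). HK2, encoding a hexokinase, rose from 2.83 ± 0.33 to 82.7 ± 3.83 FPKM and LDHA, encoding a lactate dehydrogenase subunit, from 83.9 ± 6.04 to 574 ± 33.5 FPKM. PDK1, encoding a pyruvate dehydrogenase kinase, rose by a log2 fold change of 0.80. The single member that fell was the muscle phosphofructokinase PFKM, by 0.48 on the log2 scale, and it did not pass the threshold under TMM.

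Genes of the HIF pathway itself split, 4 higher and 4 lower among 9 tested (camera adjusted p = 0.22). HIF1A, encoding the HIF-1 alpha subunit, fell from 29.1 ± 1.88 to 4.73 ± 0.26 FPKM (SD, n = 4), a log2 change of -2.39. EPAS1, encoding HIF-2 alpha, rose from 99.7 ± 2.37 to 129.7 ± 4.0 FPKM. Antisense genes lie at HIF1A, and how strand was used in the counting was not stated. The prolyl hydroxylase genes EGLN1 and EGLN3 rose. EGLN1 went from 9.29 ± 0.11 to 32.7 ± 0.62 FPKM and EGLN3 from 0.02 ± 0.02 to 2.52 ± 0.46 FPKM. HIF1AN, whose product hydroxylates HIF on asparagine, fell by 1.33 on the log2 scale. VHL, whose product recognises hydroxylated HIF, fell by 1.18, but was not past the threshold under quantile normalization (adjusted p = 0.0975).
Across the wider family of 2-oxoglutarate dioxygenases, the class of enzymes that DMOG inhibits, 18 of 34 genes rose and 10 fell. Their median lay 0.49 above that of all genes (adjusted p = 7.71e-05, and adjusted p = 0.0472 with an estimated correlation). The collagen prolyl hydroxylase P4HA1 rose from 20.4 ± 1.57 to 183 ± 1.62 FPKM and the histone demethylase KDM3A from 2.90 ± 0.15 to 18.0 ± 0.42 FPKM. P4HA2, the lysyl hydroxylase PLOD2 and JMJD6 also rose, by log2 fold changes of 1.52, 1.12 and 1.73. RIOX1, a ribosomal oxygenase, and the histone demethylase KDM6A fell by 1.91 and 0.89 on the log2 scale.

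Angiogenesis genes rose more than other genes, with 17 of 25 higher and 7 lower. The median lay 0.96 above that of all genes (adjusted p = 1.44e-06, and adjusted p = 0.0149 with an estimated correlation). Besides ADM, ANGPTL4 and VEGFA, the lymphatic growth factor VEGFC rose from 20.1 ± 0.92 to 92.5 ± 0.91 FPKM, the peptide hormone APLN from 39.1 ± 3.07 to 158 ± 8.46 FPKM. The placental growth factor PGF and the chemokine receptor CXCR4 rose by log2 fold changes of 2.27 each. KDR, the main VEGF receptor of endothelium, fell from 29.4 ± 0.94 to 6.68 ± 0.15 FPKM. PDGFB, a growth factor that attracts pericytes, fell by 0.79 on the log2 scale.
Endothelial identity genes went both ways, 6 higher and 18 lower of 25 (camera adjusted p = 0.447, but adjusted p = 0.0101 under quantile normalization). The transcription factor ETS1 rose by a log2 fold change of 2.32 and the junctional cadherin CDH5 from 154 ± 8.33 to 388 ± 10.1 FPKM. The angiopoietin receptor TEK rose from 49.9 ± 1.69 to 70.7 ± 3.93 FPKM. The C-type lectin CLEC14A fell from 108 ± 3.38 to 20.6 ± 1.18 FPKM. The transcription factors TAL1, SOX17 and ERG fell by 1.99, 1.48 and 1.37 on the log2 scale. PECAM1, an adhesion molecule of endothelial junctions, had a log2 fold change of -0.03 (adjusted p = 0.387). It passed the threshold upward under TMM, at 0.43, and downward under quantile normalization, at -0.21.
Arterial and Notch pathway genes were 7 higher and 9 lower of 17 (camera adjusted p = 0.365), and 8 higher and 7 lower under TMM. The Notch ligand DLL4 and the Notch target HES1 rose by log2 fold changes of 1.71 and 1.84. The Notch target HEY2, the gap junction gene GJA4 and the arterial kinase BMX fell by 2.01, 2.13 and 2.31 on the log2 scale. No gene of the venous and lymphatic list rose (1 did under TMM) and 5 of 7 fell, or 6 of 7 adjusted over the list alone (camera adjusted p = 0.193). VCAM1 and the venous ephrin receptor EPHB4 fell by 1.73 and 1.46 on the log2 scale. Junction and barrier genes were 5 higher and 10 lower of 18 (camera adjusted p = 0.564), and 8 higher and 6 lower under TMM. The tight junction gene CLDN5 fell by 1.91 on the log2 scale.

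Genes of vascular tone were 4 higher and 8 lower of 15 (camera adjusted p = 0.425), and 7 higher and 6 lower under TMM. NOS3, encoding the endothelial nitric oxide synthase, fell from 25.4 ± 2.02 to 6.33 ± 0.88 FPKM and EDN1, the gene of the vasoconstrictor endothelin-1, from 385 ± 15.9 to 216 ± 8.79 FPKM. ARG2, an arginase that competes with nitric oxide synthase for arginine, rose from 0.95 ± 0.41 to 13.03 ± 0.49 FPKM. The prostacyclin synthase PTGIS rose by a log2 fold change of 1.08.
BMP and TGF-beta genes were 9 higher and 11 lower of 23 (camera adjusted p = 0.177), and 12 higher and 5 lower under TMM. Among them ID1, a target of BMP signaling, fell from 119 ± 6.77 to 13.9 ± 1.23 FPKM and ID3 fell by 1.41 on the log2 scale. ID2, of the same family, rose from 3.48 ± 0.54 to 39.1 ± 4.38 FPKM. The pathway inhibitors SMAD7 and NOG rose by log2 fold changes of 3.09 and 2.73, and the ligand gene BMP2 fell by 1.68 on the log2 scale. BMPR2, the receptor gene mutated in heritable pulmonary arterial hypertension, had 17.8 ± 3.21 FPKM in Control and 19.3 ± 1.58 FPKM in DMOG (adjusted p = 0.412). It passed the threshold under TMM with a log2 fold change of 0.56.
Genes that respond to blood flow through KLF2 were 5 higher and 7 lower of 14 (camera adjusted p = 0.364), and 7 higher and 6 lower under TMM. KLF2 rose from 20.01 ± 1.22 to 91.1 ± 3.59 FPKM and KLF4 by a log2 fold change of 3.11. CYP1A1, a target of the aryl hydrocarbon receptor, fell by 2.15 on the log2 scale.

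**Figure D2:**
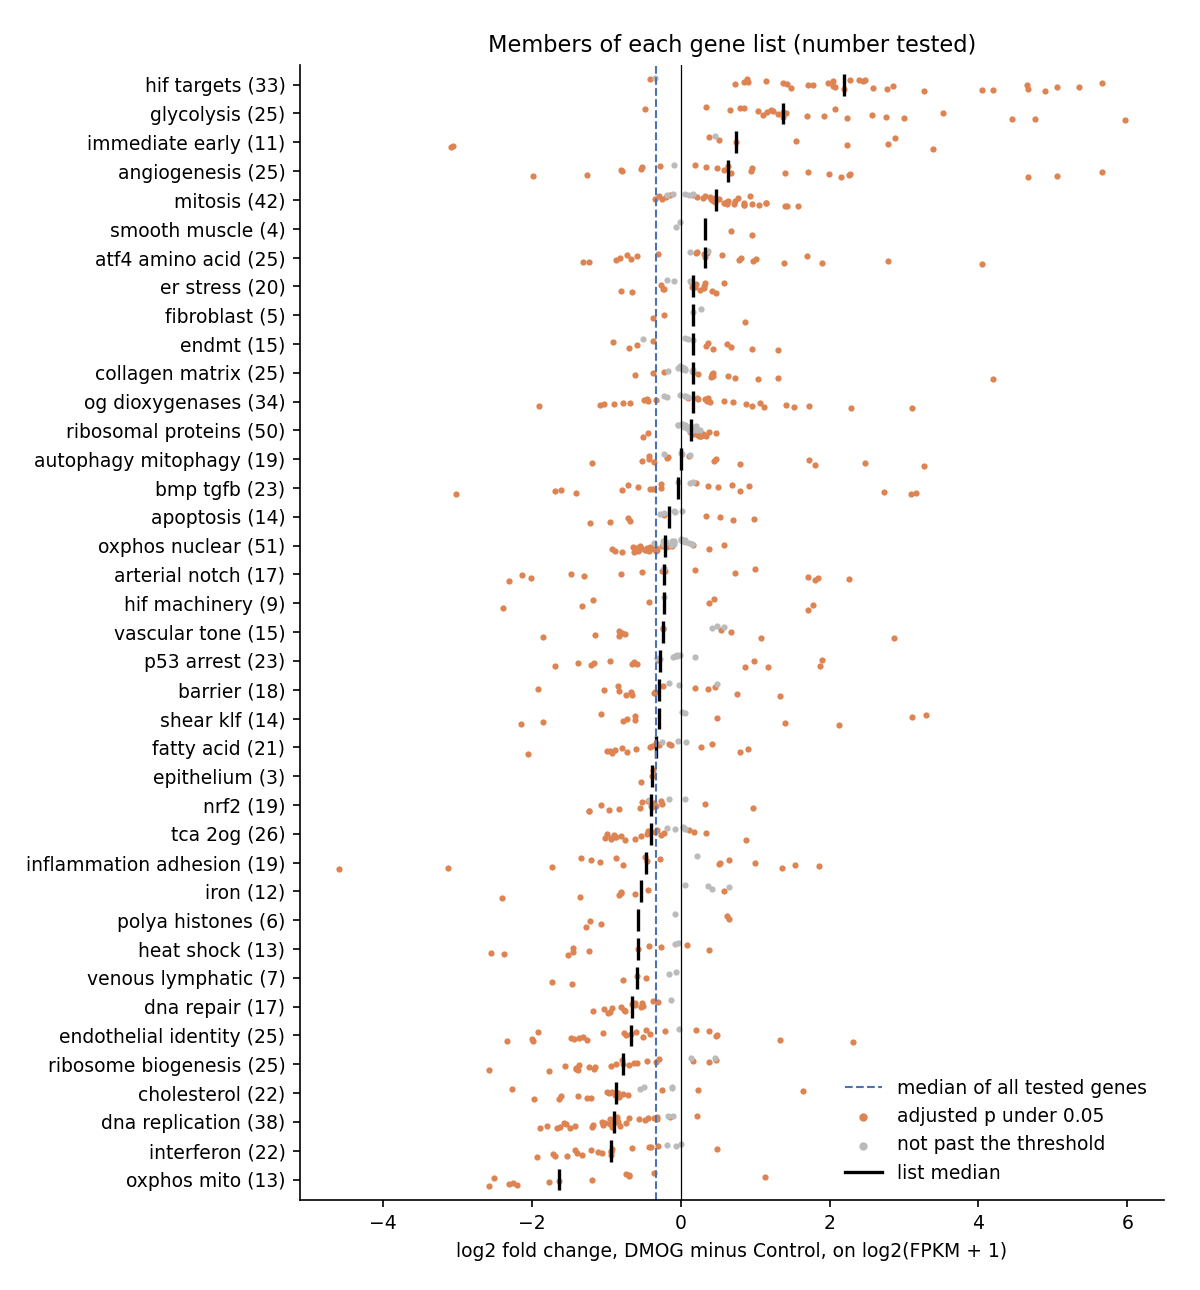
Log2 fold change, DMOG minus Control, of each tested member of the fixed gene lists with at least 3 tested members, 1 point per gene, colored by whether it passed the threshold, with a bar at the list median and a dashed line at the median of all tested genes (-0.33). HIF targets and glycolysis lie farthest right and the 13 mitochondrially encoded subunits farthest left, and lists near the dashed line changed their balance of higher and lower genes with the scaling, such as the nuclear oxidative phosphorylation genes (3 higher and 26 lower as deposited, 23 higher and 4 lower under TMM).

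DNA replication genes fell, 35 of 38, and their median relative to all genes was -0.57 (adjusted p = 0.000158, and adjusted p = 0.0283 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, fell from 53.1 ± 7.87 to 14.5 ± 1.15 FPKM, the helicase subunit MCM3 from 17.3 ± 0.51 to 4.76 ± 0.29 FPKM, and the flap endonuclease FEN1 from 12.7 ± 0.42 to 2.68 ± 0.16 FPKM. The 1 replication gene that was higher, CDT1, had a log2 fold change of 0.22 and did not pass the threshold without Control replicate 1, 2 or 4 or DMOG replicate 2 or 4 (adjusted p from 0.0745 to 0.108). Mitosis genes rose, 32 of 42, with 5 lower, and their median lay 0.80 above that of all genes (adjusted p = 3.65e-13). The call was lost with an estimated correlation (adjusted p = 0.06). UBE2C, which loads ubiquitin on mitotic cyclins, rose from 14.9 ± 0.99 to 46.7 ± 1.58 FPKM. So did the proliferation marker MKI67 from 6.98 ± 0.52 to 20.5 ± 1.19 FPKM and CCNA2 from 19.2 ± 1.05 to 40.9 ± 2.17 FPKM. DNA repair genes fell, 16 of 17 (adjusted p = 0.00964, and adjusted p = 0.162 with an estimated correlation). Under quantile normalization only 9 fell and 1 rose, and the call was lost (adjusted p = 0.0512). Among them EXO1 fell by 1.18 and BRCA1 by 0.95 on the log2 scale. Genes of p53 and cell cycle arrest were 5 higher and 10 lower of 23 (camera adjusted p = 0.5), and 11 higher and 8 lower under TMM. The inhibitor CDKN1A and the stress gene GADD45A rose by log2 fold changes of 0.86 and 1.88. MDM2, whose product degrades p53, fell by 1.17 on the log2 scale. Of 6 histone genes that can carry poly(A) tails, 2 rose and 3 fell, including H2AC6 by 1.28 on the log2 scale (camera adjusted p = 0.692). Their median lay below that of all genes while the set test pointed up.

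Inflammatory genes split in 19 tested, 7 higher and 11 lower, and 9 higher and 8 lower under TMM. Besides CCL2, the neutrophil chemokine CXCL1 fell from 124 ± 4.41 to 13.3 ± 1.40 FPKM and VCAM1, an adhesion molecule for leukocytes, from 4.83 ± 0.27 to 0.76 ± 0.14 FPKM. The related chemokines CXCL8 and CXCL2 rose by log2 fold changes of 1.36 and 1.86, CXCL8 from 78.1 ± 0.88 to 203 ± 7.71 FPKM. The list did not stand apart from other genes (camera adjusted p = 0.347), and its median lay below that of all genes while the set test pointed up. Interferon response genes fell, 18 of 22 with 1 higher (IRF7), and their median relative to all genes was -0.60 (adjusted p = 0.0151). The call was lost with an estimated correlation (adjusted p = 0.241) and with the filter at 5 FPKM (adjusted p = 0.0688). IFIT5 and XAF1 fell by 1.94 and 1.71 on the log2 scale. Immediate early genes were 8 higher and 2 lower of 11. Their median lay 1.07 above that of all genes (adjusted p = 0.000182, and adjusted p = 0.0787 with an estimated correlation). DUSP1, encoding a phosphatase of MAP kinases, rose from 28.4 ± 1.74 to 307 ± 9.04 FPKM, and the AP-1 genes FOSL2 and JUNB rose by log2 fold changes of 2.88 and 2.23. The 2 that fell were the transcription factor EGR1, from 8.28 ± 0.53 to 0.11 ± 0.07 FPKM, and IER2, from 18.5 ± 0.81 to 1.30 ± 0.14 FPKM.

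Mitochondrial transcripts fell unequally. The mitochondrial genome supplied 25.3 ± 0.84% of all FPKM in Control and 15.9 ± 0.28% in DMOG (SD, n = 4, exact two-sided permutation p = 0.0286). Of the 13 mitochondrially encoded subunits of oxidative phosphorylation, 12 fell (11 under TMM) and 1 rose, and their median relative to all genes was -1.30 (adjusted p = 0.00251, and adjusted p = 0.339 with an estimated correlation). MT-ND2 fell from 2071 ± 105 to 346 ± 9.45 FPKM and MT-ND6, encoded on the other strand, from 2751 ± 139 to 483 ± 59.4 FPKM. MT-CO1 fell by 0.70 on the log2 scale. MT-ND4 fell by 0.36 as deposited but did not fall under TMM, where its log2 fold change was 0.095. MT-ATP6, which shares bases with MT-ATP8, rose from 1563 ± 139 to 3405 ± 80.6 FPKM, while MT-ATP8 fell from 5983 ± 192 to 2615 ± 77.5 FPKM. Both mitochondrial ribosomal RNAs rose, MT-RNR1 by a log2 fold change of 0.94 and MT-RNR2 by 0.82. Of the 22 transfer RNA genes 20 fell, with a median log2 fold change of -3.79. Nuclear genes of oxidative phosphorylation were 3 higher and 26 lower of 51 and did not stand apart (camera adjusted p = 0.749). Under TMM their direction turned, with 23 higher and 4 lower. SDHA, a subunit of succinate dehydrogenase, rose by a log2 fold change of 0.38 and NDUFS1, of complex I, fell by 0.79 on the log2 scale. Genes of the citrate cycle and 2-oxoglutarate metabolism were 4 higher and 17 lower of 26 (camera adjusted p = 0.544), and 10 higher and 10 lower under TMM. The mitochondrial isocitrate dehydrogenase IDH2 rose from 15.4 ± 0.80 to 29.2 ± 0.96 FPKM, while its cytosolic counterpart IDH1 and the dehydrogenase OGDH fell by 0.94 and 0.90 on the log2 scale.

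**Figure D3:**
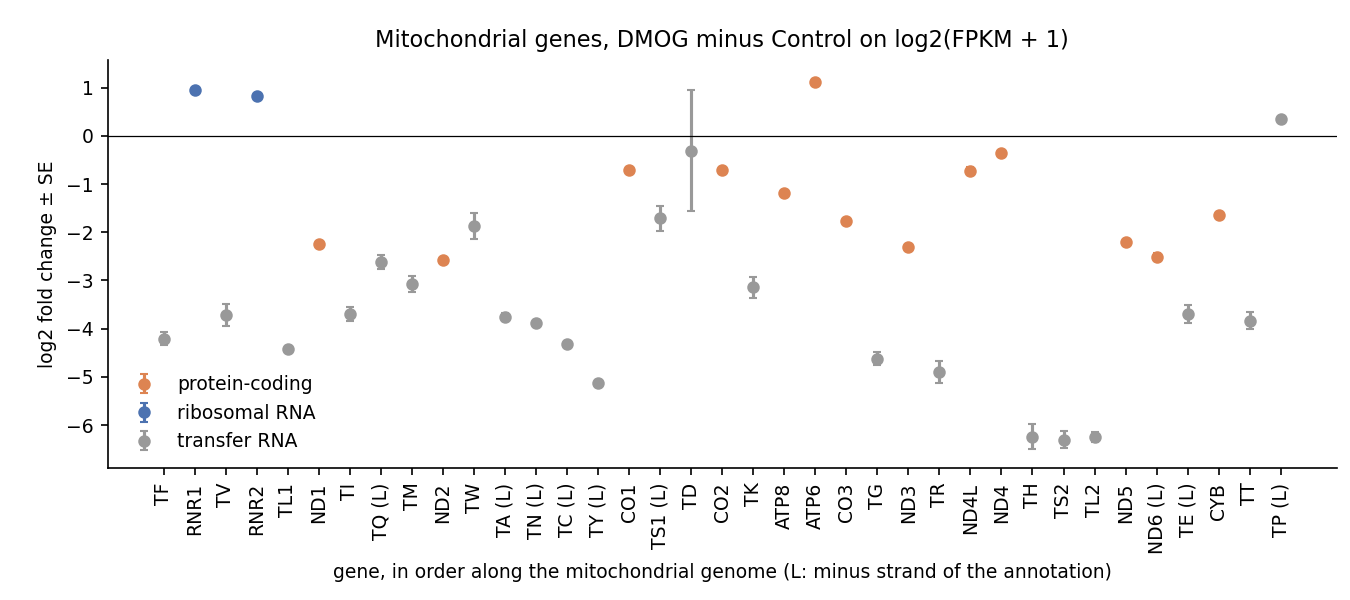
Log2 fold change, DMOG minus Control, with its standard error, of the 37 genes of the mitochondrial genome in their order along it, colored by class, with L marking genes on the minus strand of the annotation. The 2 ribosomal RNAs (0.94 and 0.82), MT-ATP6 (1.13) and MT-TP (0.34) rose, and the transfer RNAs reach -6.30 at MT-TS2.

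Cholesterol synthesis genes fell, 16 of 22 with 2 higher (15 and 5 under TMM), and their median relative to all genes was -0.54 (adjusted p = 0.0363, and adjusted p = 0.241 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 8.39 ± 0.47 to 1.40 ± 0.16 FPKM and the squalene epoxidase SQLE from 19.7 ± 0.48 to 5.70 ± 0.21 FPKM. INSIG1, an inhibitor of the pathway, rose from 7.53 ± 0.58 to 27.1 ± 12.2 FPKM. Fatty acid genes were 4 higher and 14 lower of 21 (camera adjusted p = 0.692), and 8 higher and 8 lower under TMM. The elongase ELOVL6 fell by 2.05 on the log2 scale and the desaturase SCD rose by a log2 fold change of 0.80. Amino acid response genes under ATF4 went both ways, with 15 of 25 higher, or 16 adjusted over the list alone, and 8 lower. Their median lay 0.65 above that of all genes (adjusted p = 0.000158, and adjusted p = 0.0472 with an estimated correlation). ATF4 rose from 104 ± 1.86 to 275 ± 20.3 FPKM, and ATF3, STC2 and DDIT3 rose by log2 fold changes of 2.78, 4.05 and 1.70. STC2 is also in the list of HIF targets. The cystine transporter SLC7A11 and the transfer RNA synthetase WARS1 fell by 1.23 and 1.32 on the log2 scale. CEBPG, PSPH and CHAC1, of the same list, fell by 0.86, 0.81 and 0.59. Chaperones and other genes of endoplasmic reticulum stress were 12 higher and 5 lower of 20, with a median 0.50 above that of all genes (adjusted p = 0.0039, and adjusted p = 0.06 with an estimated correlation). The call was also lost under quantile normalization (adjusted p = 0.11) and with the filter at 5 FPKM (adjusted p = 0.0515). HSP90B1, the chaperone GRP94, rose by a log2 fold change of 0.47.

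Heat shock genes were 2 higher and 9 lower of 13, and 5 higher and 7 lower under TMM (camera adjusted p = 0.213). The list passed the threshold downward under quantile normalization (adjusted p = 0.0166) and without a filter (adjusted p = 0.0128). The chaperone HSP90AA1 fell from 202 ± 10.5 to 73.5 ± 3.54 FPKM and its partner DNAJA1 from 94.8 ± 2.53 to 32.5 ± 1.26 FPKM. HSPA1A and HSPA1B, near-identical copies between which the counting could have split reads, fell by 2.54 and 2.38 on the log2 scale. NRF2 targets, genes of defence against oxidants, were 2 higher and 14 lower of 19, or 15 lower adjusted over the list alone, and 5 higher and 6 lower under TMM (camera adjusted p = 0.253). It too passed under quantile normalization (adjusted p = 0.0312) and without a filter (adjusted p = 0.0141). PRDX1, a peroxiredoxin, fell from 391 ± 4.02 to 165 ± 7.59 FPKM and the glutathione synthesis gene GCLM by 0.96 on the log2 scale. Iron genes were 1 higher and 7 lower of 12, or 3 higher and 7 lower adjusted over the list alone, and 4 higher and 6 lower under TMM (camera adjusted p = 0.692). SLC40A1, the iron exporter ferroportin, fell from 5.54 ± 0.12 to 0.23 ± 0.03 FPKM. TFRC, the transferrin receptor, rose by a log2 fold change of 0.59. Autophagy and mitophagy genes were 8 higher and 7 lower of 19, and 13 higher and 1 lower under TMM. Their median lay 0.34 above that of all genes (adjusted p = 0.00937, but 0.123 with an estimated correlation and 0.0595 with the filter at 5 FPKM, both as adjusted p). The mitophagy receptor BNIP3L rose from 27.6 ± 9.91 to 149 ± 2.93 FPKM. Another such receptor, FUNDC1, fell by 1.20 on the log2 scale. The largest rises of this list, BNIP3 and BNIP3L, are also in the list of HIF targets. The list's own median log2 fold change was 0.01, and the list was not tested without these genes. Apoptosis genes were 4 higher and 5 lower of 14 (camera adjusted p = 0.425), and 8 higher and 4 lower under TMM. The caspase gene CASP8 fell by 1.21 on the log2 scale.

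Of 50 ribosomal protein genes 21 rose and 2 fell, or 18 and 2 adjusted over the list alone. Under TMM 48 rose and under quantile normalization 13. The median lay 0.47 above that of all genes (adjusted p = 3.12e-08). The call was lost with an estimated correlation (adjusted p = 0.306) and under quantile normalization (adjusted p = 0.444). Ribosome biogenesis genes were 3 higher and 20 lower of 25, or 4 and 20 adjusted over the list alone. Their median relative to all genes was -0.45 (adjusted p = 0.0451, and adjusted p = 0.126 with an estimated correlation). RRS1, NOP56 and NOLC1 fell by 2.58, 1.77 and 1.41 on the log2 scale. This call was also lost with the filter at 5 FPKM (adjusted p = 0.0688), with the replicate block (adjusted p = 0.0546) and without Control replicate 2, DMOG replicate 2 or DMOG replicate 4 (adjusted p from 0.0503 to 0.0553).

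Matrix genes were 12 higher and 3 lower of 25 (21 and 1 under TMM), with a median 0.49 above that of all genes. The set test gave an adjusted p of 5.1e-06, and the call was lost with an estimated correlation (adjusted p = 0.123). Besides LOX, fibronectin (FN1) rose from 386 ± 13.6 to 962 ± 63.8 FPKM and the matricellular gene CCN1 from 513 ± 10.2 to 1053 ± 35.4 FPKM. Genes of endothelial-to-mesenchymal transition were 7 higher and 4 lower of 15 (10 and 3 under TMM), with a median 0.49 above that of all genes (adjusted p = 0.00408, and adjusted p = 0.0613 with an estimated correlation). TAGLN and ACTA2, contractile genes that smooth muscle also expresses, rose by log2 fold changes of 0.96 and 0.67. The transcription factor ZEB1 fell by 0.91 on the log2 scale. Markers of other cell types were few. Of 4 smooth muscle genes tested, the same TAGLN and ACTA2 rose (adjusted p = 0.0499, and adjusted p = 0.162 with an estimated correlation). This call was also lost under quantile normalization (adjusted p = 0.0512), with the filter at 5 FPKM (adjusted p = 0.132) and with the replicate block (adjusted p = 0.0529). So it was after rescaling to the sum of nuclear genes (adjusted p = 0.0542), with mitochondrial genes left out (adjusted p = 0.056), and without Control replicate 2 or DMOG replicate 1, 2 or 4 (adjusted p from 0.0553 to 0.0689). Fibroblast genes were 1 higher and 2 lower of 5, and 2 higher and 0 lower under TMM (camera adjusted p = 0.264). POSTN, a matrix gene, rose from 226 ± 5.71 to 412 ± 32.6 FPKM. All 3 tested epithelial genes, including KRT19, fell, but 0 of 3 passed the threshold under TMM (camera adjusted p = 0.404). The single leukocyte gene past the expression filter, CD68, had a log2 fold change of -0.42 (adjusted p = 0.11), which passed the threshold without Control replicate 1 (-0.63, adjusted p = 0.00364). No erythroid gene passed the filter.

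The deposited table carried its own comparison of DMOG with Control. Its significance flag marked 4914 genes, 780 higher and 4134 lower in DMOG, and these were the genes with a deposited p under 0.05 and at least a 2-fold ratio. Of them 1087 had less than 1 FPKM in all 8 libraries and were not tested here. Of the 3358 that were tested, 3340 changed, all in the same direction. A deposited q under 0.05 was given to 8423 genes, 3385 higher and 5038 lower by the deposited ratio. The q did not always follow that ratio. PECAM1 and BMPR2, with overlapping groups and deposited log2 ratios of -0.028 and 0.115, had a deposited q of 0.000248 and 0.000259. EDN1, without overlap and at -0.832, had a weaker deposited q of 0.00668. The direction behind each q is therefore not known from the ratio. Of the 6792 tested genes with a deposited q under 0.05, only 5227 changed in the fit, all in the direction of the deposited ratio. Across the 11209 tested genes, which are not independent replicates, the deposited and the fitted log2 fold changes had a Pearson correlation of 0.912. Both were computed from the same FPKM values, so this correlation and the shared directions are no independent check. For VEGFA the deposited log2 ratio was 5.71 and the fitted one 4.66, for HIF1A they were -2.62 and -2.39, and for KDR -2.14 and -1.99.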

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

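Tests of the mitochondrial transcripts, of sequencing depth and of scaling by mitochondrial genes were written only after those results had been seen, and the others before. Chance as the source of the counts of changed genes was examined with other groupings of the libraries. The real grouping was the only 1 of the 35 splits of the 8 libraries into 4 and 4 to give as many. It gave 8197 genes (1985 higher, 6212 lower, 2113 at least 2-fold), and the highest other split gave 2 genes for each of these counts. Every other split mixes DMOG with Control libraries, so their difference adds to the spread within its parts and leaves few calls. The margin in gene counts therefore does not measure chance. As 1 split of 35 is the smallest share possible, chance is not excluded for these counts. For the gene lists the real grouping gave 19 past the threshold and the highest other split 16. There too 1 split of 35 was as large, the smallest share these splits can give, so chance is not excluded. The 16 splits that kept 3 of the 4 Control libraries together gave 13 to 16 lists. They still carry part of the difference between DMOG and Control, so the margin over them does not measure chance. The 18 splits that mixed the groups evenly gave 0 to 3 lists.

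Coding genes without introns fell further than others. Of 138 with 1 exon, 22 rose and 99 fell, with a median log2 fold change of -1.01 (95% bootstrap interval -1.25 to -0.83), against -0.54 for 272 genes with 2 exons and -0.33 for 4616 with over 10. Genomic DNA in the Control libraries is argued against, since 381 olfactory receptor genes, a largely silent family without introns in the coding sequence, differed by 0.0021 FPKM (0.0007 to 0.0042) while the intronless genes lost a median of 2.6 FPKM. GC content, transcript length and level are argued against too: the intronless genes lay -0.69 (-0.92 to -0.34) from multi-exon genes matched on all of them. Reads of an overlapping gene on the other strand are argued against as the only source. Intronless genes without any annotated overlap still lay -0.58 (-0.82 to -0.25) from multi-exon genes without one. The interval is wide, and such reads stay open as a part of the fall of intronless genes that do overlap another gene. A biological difference, such as faster turnover of these transcripts under DMOG, may account for the rest but was not tested.

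The transcripts of the mitochondrial genome did not fall together. A lower total amount of mitochondrial RNA could not give this alone, since the log2 fold changes of the 13 coding genes and 2 ribosomal RNAs spanned 3.7 and 3 of these 15 rose. Lower capture of short RNA without poly(A) tails stays open for the transfer RNAs. In its test, 44 nuclear small nucleolar and small nuclear RNA genes had a median of -0.41 (-0.79 to -0.06) against -3.79 for the transfer RNAs. Those nuclear genes were not screened for overlap with other genes. Their reads may be those of longer transcripts, so the test cannot decide. Reads shared between overlapping genes are argued against as the source of the spread, since the 10 coding and ribosomal RNA genes without an overlap spanned 3.52 (95% interval from the standard errors 3.39 to 3.65). The values of overlapping genes, such as MT-ATP6 and MT-ATP8, stay uncertain, and reads that run from a transfer RNA into the adjoining gene were not tested. An effect of DMOG on the transcription or processing of mitochondrial RNA may be involved and was not tested.

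More genes fell than rose, 75.8% of those that changed. Lower sequencing depth of the DMOG libraries is argued against, since their estimated depth was 1.18 times that of the Control libraries. A scaling set by the mitochondrial genes is argued against too, since 78.5% of the changed genes were lower after rescaling to the sum of nuclear genes. A scaling set by abundant nuclear genes that rose stays open: after TMM rescaling 48.3% were lower, but TMM centers the fold changes whatever the cause and so decides nothing. A true fall of most transcripts per cell stays open as well and was not tested, since no spiked-in RNA was analysed here.

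In 26 of 348 groups of 4 libraries 1 library lay far from the other 3, where chance gives about 1 in 20, or 17.4 of them. The values of Control libraries were as follows. SLC2A3 had 4.524 FPKM in replicate 3 and SLC2A1 3.702 in replicate 2. CCL2 had 36.34 FPKM in replicate 2. PDK1 had 0.3524 FPKM in replicate 3 and DDIT3 6.882. BMPR2 had 13.02 FPKM in replicate 1, with the other libraries at 18.78 to 19.96, and BNIP3L had 12.8, with the others at 31.7 to 33.4. In replicate 4 P4HA1 had 22.73 FPKM, TEK 47.34, CASP8 1.326, MCM3 18.05, SQLE 20.45 and FOSL2 3.213, the last with the others at 10.04 to 10.62. Control replicate 4 also had 17423 genes with at least 0.1 FPKM, with the others at 17600 to 17605.
Among DMOG libraries, EMP1 had 40.25 FPKM in replicate 3, with the others at 5.19 to 5.67, and without that library its log2 fold change went from -3.47 to -4.14. ATF4 had 305.0 FPKM and MT-RNR1 1405.0 in replicate 3. Replicate 2 had 0.8706 FPKM of MIR126, 30.36 of SMAD7, 0.2948 of GJA4, 45.28 of INSIG1 and 1.269 of GIMAP4, the last 2 with the others at 19.8 to 22.2 and at 7.40 to 7.75. EGLN1 had 31.81 FPKM and STC2 75.66 in replicate 1, and FEN1 had 2.434 in replicate 4. The 10 most abundant genes took 21.6% of FPKM in DMOG replicate 2, with the others at 21.01 to 21.09.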

How the results depend on the processing

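The rescaling to nuclear genes and the left-out mitochondrial genes were chosen after seeing the data, and the other alternatives were planned. Counts kept within 1.5 times of the reported ones except where given here, and no list changed direction past the threshold. With pseudocounts of 0.1 and 0.01, 3347 (2789 lower) and 3476 (2898 lower) genes changed at least 2-fold, because a smaller pseudocount shrinks low genes less. With the filter at 5 FPKM 4422 of 6002 tested genes changed (3041 lower) and 1183 at least 2-fold (874 lower), because fewer genes were tested. TMM gave 4158 genes higher and 3880 lower, 848 and 823 at least 2-fold, and 400 genes called in both fits had opposite signs. Quantile normalization gave 3580 higher and 4071 lower, 715 and 780 at least 2-fold, with 201 such genes. Both shift the median of all genes, from -0.33 to 0.03 and -0.03. WSB1 and MT-ND4 reversed to 0.023 and 0.095 under TMM. Of the lists, 6 passed with an estimated correlation and 38 with fry, which does not compare a list with other genes. The authors' q under 0.05 marked 8423 genes against 4914 by their flag, which asks for a deposited p under 0.05 and at least 2-fold. A deposited q under 0.05 with at least 2-fold marked 4775. Without any filter 11263 of 27664 genes changed, and at an adjusted p of 0.01 7146 did. Leaving out each library in turn gave 7948 to 8024 changed genes, 1890 to 1932 higher and 6031 to 6103 lower, 2102 to 2139 at least 2-fold (406 to 424 higher, 1689 to 1720 lower), and 17 to 19 lists. Lists also lost the threshold under the 5 FPKM filter (5 lists, such as interferon at an adjusted p of 0.0688) and quantile normalization (4 lists, such as DNA repair at 0.0512 and endoplasmic reticulum stress at 0.11), while heat shock and NRF2 gained it without a filter and under quantile normalization, and endothelial identity under the latter; the cause was not tested. The replicate number as a block gave 8032 changed genes, 1930 higher and 6102 lower, and 2 lists lost the threshold, ribosome biogenesis (adjusted p = 0.0546) and smooth muscle (adjusted p = 0.0529). The deviations of same-numbered libraries correlated at -0.113, -0.021, 0.017 and -0.12, so no pairing by number was seen. A pairing that leaves no shared deviation cannot be excluded. Count-based alternatives (edgeR, DESeq2, voom) were not run, since the table holds no counts. Depth limits low genes most: below 1 FPKM in most libraries no gene was tested.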

Other observations

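GIMAP genes, GTPases of a gene cluster first known from lymphocytes, fell together, a hypothesis drawn from the fall of GIMAP7 and tested on the other members before their values were seen. All 5 other members past the expression filter fell, under every setting tried. GIMAP8 fell from 19.3 ± 0.45 to 2.50 ± 0.22 FPKM (SD, n = 4), GIMAP6 from 28.1 ± 1.06 to 7.80 ± 0.76 FPKM, and GIMAP4, GIMAP1 and GIMAP2 fell by 2.47, 1.53 and 1.39 on the log2 scale. A shared control of the cluster is a possible explanation, which the table cannot test further.

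Of the 10 largest rises, 2 were genes tied to the circadian clock, the repressor BHLHE40 and NOCT, an enzyme with a daily rhythm. BHLHE40 is also in the list of HIF targets. The repressor NFIL3 rose from 5.08 ± 0.40 to 92.7 ± 4.72 FPKM and PER1 from 3.03 ± 0.19 to 35.9 ± 4.21 FPKM, both chosen after their values were seen. Whether clock targets rose as a group stays open. The 4 other targets past the filter had a median 1.04 above that of all genes, but with an interval from -0.10 to 1.34, and circadian rhythm genes in the deposited table's annotation were 12 higher and 10 lower of 24 (adjusted p = 0.0618, and adjusted p = 0.327 with an estimated correlation). CRY2 and CIART rose by log2 fold changes of 1.01 and 0.90, CRY1 fell by 0.43 on the log2 scale but did not pass the threshold under TMM or quantile normalization, and NR1D2 had a log2 fold change of 0.51 (adjusted p = 0.143), which passed the threshold under both, at 0.91 and 0.82, and without DMOG replicate 4, at 0.84.

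Pathways named in the deposited table's own annotation were tested as well, a step not fixed beforehand. Of 262 pathways with 15 to 300 tested genes, 30 passed the threshold at the preset correlation, 23 of them upward. With an estimated correlation 0 passed, and the smallest adjusted p was 0.271. Upward is relative to other genes, whose median was -0.33, and does not mean that most members rose. MAPK signaling genes, for example, passed upward with 59 higher and 78 lower of 182. The ribosome, HIF-1 signaling and glycolysis pathways given below also passed upward. Peroxisome genes fell, 49 of 61 with 4 higher (adjusted p = 0.0331, and adjusted p = 0.3 with an estimated correlation). Mismatch repair genes fell in 20 of 22 cases (adjusted p = 0.033) and Fanconi anemia genes in 37 of 44 (adjusted p = 0.044), with adjusted p of 0.271 and 0.307 with an estimated correlation. Aminoacyl-tRNA synthesis genes were 4 higher and 32 lower of 42 (adjusted p = 0.0673). Cell cycle genes were 25 higher and 65 lower of 111 (adjusted p = 0.595), and ribosome genes 35 higher and 39 lower of 129 (adjusted p = 0.0263, and adjusted p = 0.558 with an estimated correlation). The pathway that table calls HIF-1 signaling was less one-sided than the list of HIF targets, with 33 higher and 29 lower of 75 (adjusted p = 0.00181, and adjusted p = 0.271 with an estimated correlation). So was its glycolysis and gluconeogenesis pathway beside the fixed list of glycolysis genes, with 17 higher and 20 lower of 41 (adjusted p = 0.0331, and adjusted p = 0.3 with an estimated correlation).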
